A study of Mus musculus with 5 samples.

How the data were processed

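Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in 5 libraries of mouse embryonic stem cells, 1 per group. KAP1 is a corepressor encoded by Trim28, and Ring1b is a catalytic subunit of Polycomb repressive complex 1 encoded by Rnf2. KAP1 was immunoprecipitated from KAP1 fl/fl cells given vehicle or 4-hydroxytamoxifen. Ring1b was immunoprecipitated from Ring1b fl/fl cells given vehicle or 4-hydroxytamoxifen, and from KAP1 fl/fl cells given 4-hydroxytamoxifen. The fl/fl cells carry conditional alleles that the drug deletes. Per the labels' protocols, the drug was given for 24 h and the cells were then cultured for 48 h, on irradiated mouse embryonic fibroblast feeders. They were fixed for 10 min in 1.2% formaldehyde, and the chromatin was sheared to fragments of about 200 bp. The antibody amount was 5 µg for KAP1 and 3 µg for Ring1b.

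Per the submitters' processing notes, the tools were CASAVA 1.8.2, Bowtie2, MACS 1.4.2 and bedtools 2.16.2, on genome build mm10 (GRCm38). The authors deposited 3 peak lists, each called on 1 library against another library. Per the file headers, the vehicle KAP1 library was called against the tamoxifen KAP1 library, and the vehicle Ring1b library against the tamoxifen Ring1b fl/fl library. The Ring1b library of KAP1 fl/fl tamoxifen cells was called against Ring1b from Ring1b fl/fl tamoxifen cells, a different cell line. That last list is called the knockout list here. The score of each peak is 10 times the -log10 p that the authors computed with MACS for that library against its control, as deposited and per the file headers. It ranks peaks within 1 list only. The commonest score of the Ring1b list was 3100, carried by 732 peaks, so many high-scoring Ring1b peaks are tied. The highest score of that list was 3233. Whether the tied peaks are weaker than those with scores above 3100 is not known here. The authors also deposited 6 gene tables, which put promoters and whole genes into classes with both proteins, KAP1 only or Ring1b only. The scores in those tables are in the same deposited unit. The tables were checked against the peak lists. Of the KAP1 regions in the shared and KAP1 only promoter tables, 39.4% and 42.2% had the same borders as a listed peak, while 96.0% and 97.3% had the same summit. The origin of the other borders is not given in the sources used here.

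Read depths of the libraries are not given in the sources used here, and intervals cover counting error over peaks or genes only. With 1 library per group, no difference between conditions was tested. Peaks and genes are not replicates, and every p-value describes the lists compared. Intervals on shares are exact (Clopper-Pearson) at the 95% level. Where a share was 0, the limit was set at 3 counts of the total.

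Overlap meant at least 1 bp in common. Ring1b peaks were placed at random 1000 times on their own chromosomes with their widths kept, within the span covered by peaks and annotated genes. The share overlapping KAP1 was compared with those placements (permutation test, one-sided, smallest p 0.001). Gene names and gene coordinates came from a RefSeq table of GRCm38.p6, the build of the files. Of the 13039 deposited promoter regions, 12939 matched it by accession and 100 did not. The gene set was the 21035 protein-coding symbols with a RefSeq mRNA. A promoter was a deposited region of 1 kb on each side of a transcript start, and a gene with promoters in more than 1 class counts in each. Co-occupancy over genes was tested with Fisher's exact test (two-sided), with genes in no table as neither. The reference used here gives neither strand nor exons. Exons and introns were therefore merged as gene body, and transcript starts of genes in no table were not placed.

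Before the data were examined, 20 gene lists were fixed, 14 by symbol and 6 by symbol pattern. Each list was tested in each promoter class against all other genes (Fisher's exact test, two-sided), with Benjamini-Hochberg adjustment over the 60 tests and a threshold of 0.05. Kept Ring1b peaks were those overlapping a knockout-list peak. Their relation to KAP1 was tested with Fisher's exact test and summarised as a Mantel-Haenszel odds ratio over 10 deciles of score. Differences of medians within a list were tested by permutation with 100000 resamples (two-sided). Odds ratio intervals are Woolf's, with 0.5 added to each cell where one was 0.

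The genes named were set by rule before the data were examined. They are 20 fixed genes, up to 4 members of each list with the highest-scoring promoter peak (ties by symbol), and the 5 highest-scoring peaks of each class, named by the gene that contains or lies nearest to them. Peaks on unplaced contigs were not named, and some genes that meet the rule are not reported here. Alternatives fixed in advance were an overlap of 50% of the peak, a distance of 1 kb, the upper 50% of scores, equal numbers of top peaks, autosomes only, merged peaks, wider promoters, other gene classes or backgrounds, and width deciles. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated data, the placement test of 13516 peaks called 2 of 20 unplanted and 20 of 20 planted sets. The list test on 21000 genes called 3 of 300 unplanted and 100 of 100 planted lists.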

Results

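The data describe where KAP1 and Ring1b sat in the genome of mouse embryonic stem cells, which are pluripotent cells able to form every tissue of the embryo. The deposited lists held 82775 KAP1 peaks and 13516 Ring1b peaks in vehicle-treated cells, each called against cells of the same line in which the protein's own gene was deleted. A further 8928 Ring1b peaks were called in KAP1 knockout cells. The KAP1 list covered 49.9 Mb with a median width of 512 bp. The Ring1b list covered 14.2 Mb with a median width of 587 bp, and 247 of its peaks were 5 kb or wider, against 12 KAP1 peaks. The knockout list covered 1.92 Mb with a median width of 158 bp. Each list rests on 1 library and its control, so no value has a replicate error. Scores are 10 times the authors' -log10 p and rank peaks within 1 list only.

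The deleted genes themselves had promoter peaks of both proteins, each mapped in vehicle cells of its own fl/fl line. At Trim28 (chromosome 7, 13024152 to 13031032), which encodes KAP1, the promoter held a KAP1 peak with a score of 199 and a Ring1b peak with a score of 209. At Rnf2 (chromosome 1, 151469398 to 151500991), which encodes Ring1b, the promoter scores were 304 for KAP1 and 86.7 for Ring1b. Neither promoter had a peak in the knockout list. Peak lists give no expression, so these values do not check the deletions.

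The first comparison asked how far KAP1 and Ring1b share binding sites. KAP1 was mapped in vehicle KAP1 fl/fl cells and Ring1b in vehicle Ring1b fl/fl cells, a different line. Overlap and co-occupancy thus compare lists across lines and do not show both proteins in the same cells. Of the 13516 Ring1b peaks, 10353 overlapped a KAP1 peak, which is 76.6% (95% exact interval 75.9% to 77.3%). Random placement of the same peaks gave a mean of 4.93%, and the observed count was 15.5 times that mean (permutation test, one-sided, p = 0.001, the smallest it can give). In the other direction, 11363 KAP1 peaks overlapped Ring1b, which is 13.7% (13.49% to 13.96%). The share with KAP1 was 68.2% in the narrowest 25% of Ring1b peaks and 80.9% in the widest 25%, beside 2.97% and 8.70% for random placement.

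The highest-scoring Ring1b peaks with KAP1 lay in Glis1 (chromosome 4, 107433666 to 107436965, score 3233), over Mab21l1 and Nbea (chromosome 3, 55781520 to 55784609), and in Prkg1, Paqr9 and Ssbp2. The highest-scoring Ring1b peaks without KAP1 lay in Adora1 (chromosome 1, 134234064 to 134236534, score 3207), 2565 bp from Hand2, 27027 bp from Rasgrf1 and in Sidt1. Hand2 encodes a transcription factor of heart and limb development. Among KAP1 peaks without Ring1b, the highest-scoring lay on chromosome Y (90736661 to 90747258, score 3100), far from any protein-coding gene used here. It was followed by peaks in Agrn, 154118 bp from Cops8, the nearest gene, and in Zfp462. The highest-scoring KAP1 peaks with Ring1b were all on chromosome 1. They lay 20373 bp from Gli2, a transcription factor of Hedgehog signalling, 547 bp from B3gnt7, 15754 bp from Inhbb, 33177 bp from Ptma and in Atp1b1. Both proteins favour gene ends. Placement limited to windows of 5 kb around the deposited promoters raised the random mean to 27.1% and lowered the ratio to 2.82 (permutation test, p = 0.001). Those promoters were deposited as carrying KAP1 or Ring1b, which raises this random mean by construction. With windows of 5 kb around either end of any protein-coding gene, chosen after seeing the data, the mean was 14.8%. The ratio was then 5.16 (permutation test, p = 0.001). With equal numbers of top peaks, 28.4% of Ring1b peaks overlapped KAP1, 25.8 times the random mean.

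**Figure D1:**
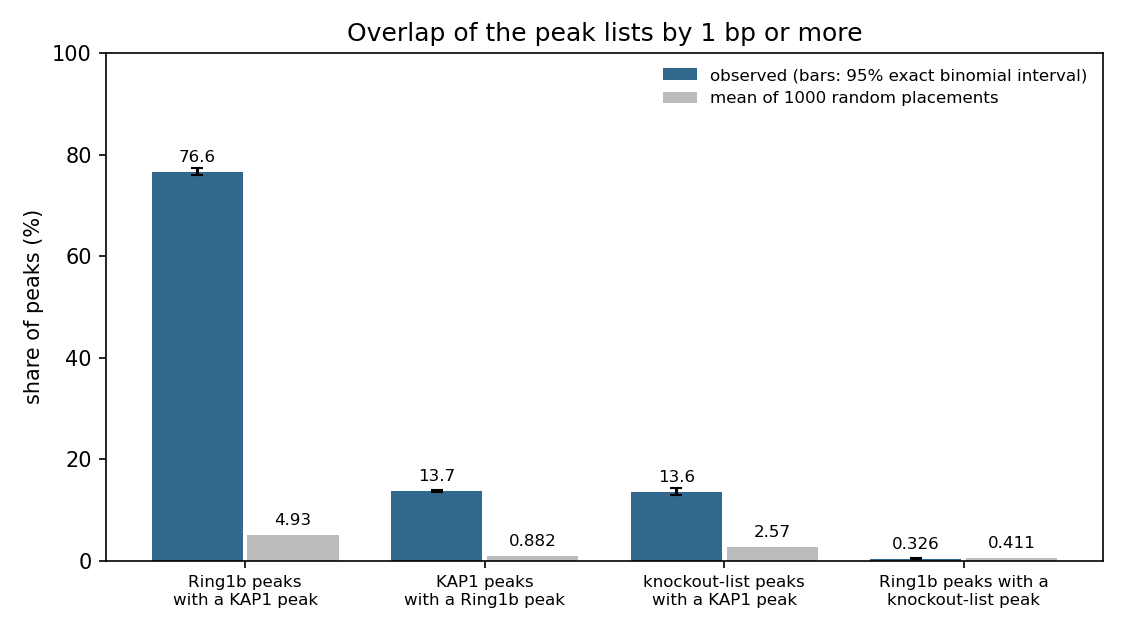
Share of peaks (percent, vertical axis) that overlap another list by at least 1 bp, for 4 comparisons. Dark bars are observed shares with 95% exact binomial intervals and grey bars are means of 1000 random placements; 76.6% of Ring1b peaks met KAP1, and 0.326% met a knockout-list peak.

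Over genes, the same co-occupancy was seen at promoters. Of the 5653 genes with Ring1b at a promoter, 86.3% also had KAP1 at one, against 40.4% of the genes without Ring1b. The odds ratio was 9.24 (8.51 to 10.0; Fisher's exact test, two-sided, with a p too small for double precision). KAP1 lay at promoters of 52.8% of the 21035 genes and Ring1b at 26.9%. The deposited tables held 5236 shared, 6919 KAP1 only and 884 Ring1b only promoters. Against the peak lists, 5235 of the shared promoters had a KAP1 peak and all 5236 a Ring1b peak, while no KAP1 only promoter had Ring1b and no Ring1b only promoter had KAP1. These shares of 0 hold for the window of 1 kb that made the classes: within 5 kb, 29.8% of the Ring1b only promoters had a KAP1 peak and 6.63% of the KAP1 only promoters had a Ring1b peak. The odds ratio fell to 3.40 (3.16 to 3.66) with only the upper scores of each list.

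Of the 20 genes fixed in advance for naming, 12 had a shared promoter, 5 a KAP1 only promoter and 3 a Ring1b only promoter. The core pluripotency factors differed among themselves. Pou5f1 (chromosome 17, 35506032 to 35510777) had a KAP1 peak with a score of 444 (35509152 to 35510220) and a Ring1b peak of 88.7 (35509355 to 35509688). Both peaks lay inside the gene, nearer its last base than its first, so they do not place either protein at the first base. Sox2 had KAP1 and Ring1b scores of 156 and 69.7. Nanog (chromosome 6, 122707489 to 122714633) and Klf4 had KAP1 without Ring1b, with scores of 128 and 353. Several regulators of differentiation had Ring1b peaks at 3100, the commonest score of that list: Gata6 (endoderm), T (mesoderm), Pax6 (neuroectoderm), Cdx2 (trophectoderm) and Hand1. Gata4 (endoderm) had a Ring1b score of 1579. KAP1 scores at those 6 promoters lay between 52.3 and 103. Sox17 (chromosome 1, 4490928 to 4497426), Nkx2-2 and Hoxa9 had Ring1b without KAP1 at the promoter, although all 3 are in the shared class over the whole gene. Hoxb13 and Hoxd13 had both proteins. Zfp57 and Peg3, an imprinting regulator and an imprinted gene, had KAP1 alone, with scores of 212 and 136, as did Actb, a cytoskeletal gene, with 251.

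The gene lists were then set against the promoter classes. Of 60 tests, 20 showed more members than other genes had and 17 showed fewer (Fisher's exact test, Benjamini-Hochberg adjusted). The shared class held more members of 10 lists. It took 16 of 21 trophectoderm regulators (76.2%, odds ratio 10.7, Fisher's exact test, adjusted p = 2.17e-06), 30 of 45 neuroectoderm regulators (66.7%, 6.68, 4.72e-09) and 25 of 38 differentiation signalling ligands (65.8%, 6.42, 1.54e-07). It took 30 of 46 mesoderm regulators (65.2%, 6.26, 9.38e-09) and 15 of 25 endoderm regulators (odds ratio 5.00, 0.000226). Examples with both proteins were Cdx2, Gata3 and Dlx3 of trophectoderm, Atoh1 and Hes5 of neuroectoderm, Eomes, Evx1 and Foxc2 of mesoderm, and Foxa1, Foxa2 and Cxcr4 of endoderm. Their KAP1 scores ran from 60.2 at Gata3 to 388 at Evx1, beside a KAP1 list minimum of 50.0 and median of 96.2. Cdx2, Gata3, Dlx3, Foxa1 and Foxa2 lay below that median, and the other examples above it. The list tests were not run with only the upper scores, so weak KAP1 calls count as much as strong ones. The ligands Bmp6 and Fgf8 had Ring1b scores of 3100 and 3136. Germline genes (23 of 41, Fisher's exact test, adjusted p = 1.99e-05), such as Mael, Meioc and Tdrd5, and pluripotency-associated genes (22 of 40, 4.13e-05), such as Pou5f1, Klf5, Esrrb and Nr5a2, were also in the shared class more often than other genes. So were Hox cluster genes (20 of 39, 0.000403) and Polycomb subunit genes (17 of 40, 0.0129), including Bmi1. Markers of fibroblasts, the feeder cells of these cultures, were there too (11 of 25, 0.0466), among them Twist1, Twist2 and Prrx1, a call that ended with whole-gene classes (Fisher's exact test, adjusted p = 0.104). Members of 6 lists were fewer in this class: numbered zinc finger, ribosomal protein, replication-dependent histone, olfactory receptor, vomeronasal receptor and totipotency-associated genes. The call for numbered zinc finger genes ended with whole-gene classes (Fisher's exact test, adjusted p = 0.155). Membership of the shared class needs Ring1b as well as KAP1. Among genes with Ring1b, 0 of 19 lists had KAP1 more often than the others and 2 had it less often, in tests chosen after seeing the data.

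The KAP1 only class held more members of 5 lists. It took 216 of 392 numbered zinc finger genes (55.1%, odds ratio 2.92, 2.39 to 3.57, Fisher's exact test, adjusted p = 3.72e-24), many of which encode transcription factors with zinc finger domains. Zfp36 and Zfp13 had promoter KAP1 scores of 465 and 436, although both are in the shared class over the whole gene. It also took 19 of 31 KAP1 pathway genes (Fisher's exact test, adjusted p = 0.00109), among them Cbx5, which encodes the heterochromatin protein HP1 alpha, and Zfp568. The others were 20 of 33 housekeeping genes (0.000815), such as Tubb5 and Eef1a1, 42 of 84 ribosomal protein genes (0.000434), such as Rpl27 and Rplp0, and 30 of 67 replication-dependent histone genes (0.0188), such as H1f2. Fewer members than other genes had were found for 9 lists, among them Hox cluster genes, with 0 of 39 (up to 3 counts allowed by 0; Fisher's exact test, adjusted p = 6.35e-06), and neuroectoderm regulators, with 1 of 45 (1.60e-05).

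The Ring1b only class was small, and 5 lists had more members there. Hox cluster genes, which pattern the body axis, had 16 of 39 (41.0%, odds ratio 17.8, 9.35 to 33.8, Fisher's exact test, adjusted p = 2.69e-12), including Hoxa2, Hoxa3, Hoxa9 and Hoxa13. Neuroectoderm regulators had 11 of 45 (8.21, 3.81e-06), including Pax7. Differentiation signalling ligands had 9 of 38 (7.86, 3.44e-05), including Bmp2, clustered protocadherin genes 11 of 57 (6.06, 3.21e-05) and mesoderm regulators 8 of 46 (5.32, 0.000721), including Foxc1. Over the whole gene, Hoxa3, Hoxa9, Pax7, Bmp2 and Foxc1 are in the shared class. Neighbouring genes can share a peak, which the list tests do not allow for, so their p-values for clustered genes are too small. Hoxa9, for example, was counted through the Ring1b peak that also covers the promoter of Hoxa10, a shared gene. The wide Ring1b peak at Hoxa2 held 7 KAP1 peaks outside its promoter window. Olfactory and vomeronasal receptor genes, which act in sensory neurons, were nearly free of both proteins at promoters: 6 of 1104 and 3 of 353 had KAP1 and 2 and 0 had Ring1b. Over the whole gene, 18 vomeronasal receptor genes were KAP1 only and 1 shared. Of the olfactory receptor genes, 5 were KAP1 only, 3 shared and 1 Ring1b only. Imprinted genes passed in no promoter class, with 16 of 43 shared (Fisher's exact test, adjusted p = 0.0677), but did pass in the shared whole-gene class, with 21 of 43 (0.00600). With whole-gene classes in place of promoters, the Ring1b only calls for mesoderm regulators (Fisher's exact test, adjusted p = 0.0937) and differentiation signalling ligands (0.0631) ended, while fibroblast markers passed (0.0233). The KAP1 only class then held fewer endoderm regulators (Fisher's exact test, adjusted p = 0.0408). Of the 57 clustered protocadherin genes, 1 is in any whole-gene class, so those classes say nothing about this list. Against genes in any class as background, the shared calls for Hox cluster (Fisher's exact test, adjusted p = 0.158), Polycomb subunit (0.521) and pluripotency-associated genes (0.0951) ended, as did the KAP1 only calls for KAP1 pathway (0.0951) and housekeeping genes (0.111). The shared calls for olfactory and vomeronasal receptor genes and the KAP1 only call for totipotency-associated genes ended too. Those lists had few members in that background.

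**Figure D2:**
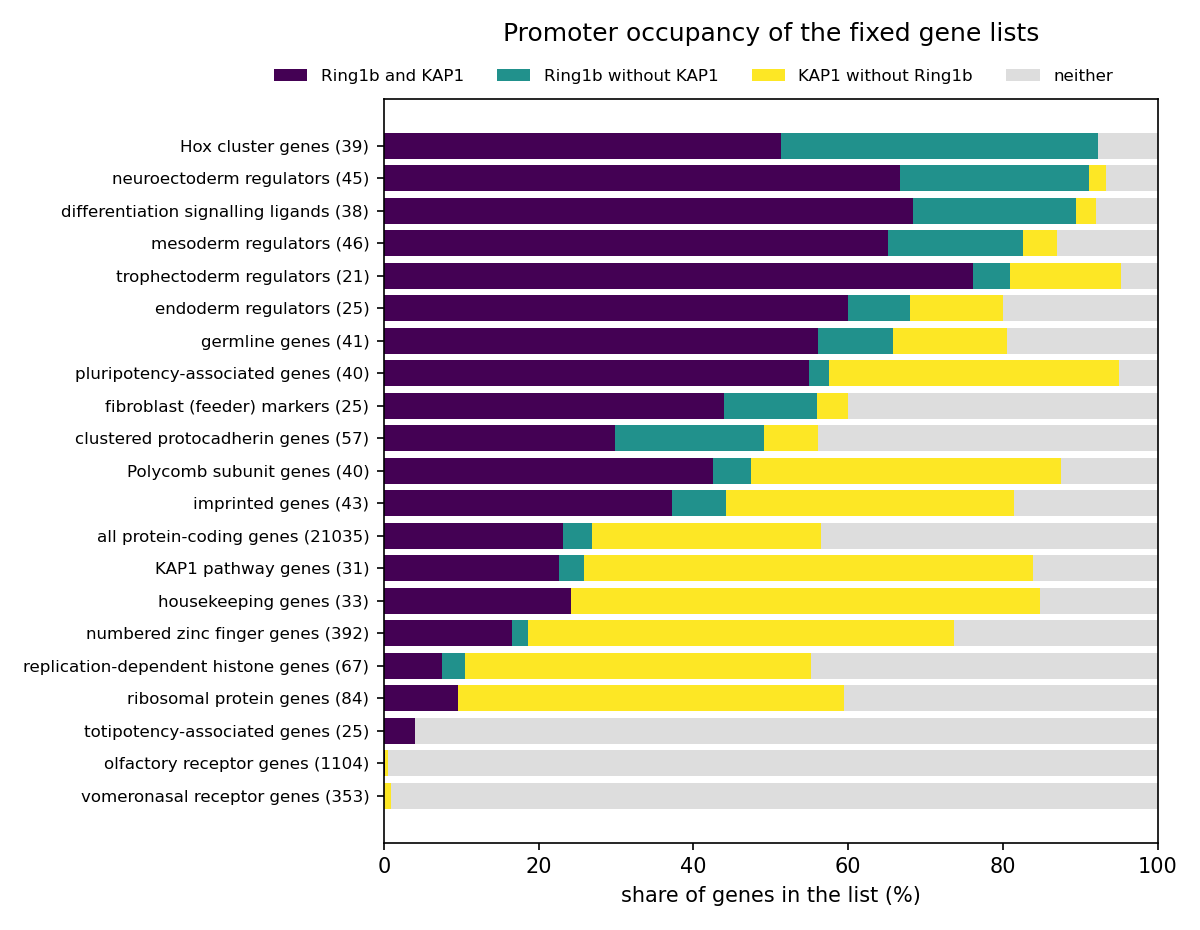
Share of the genes in each fixed list (percent, horizontal axis; number of genes in brackets) whose promoters carried Ring1b and KAP1, Ring1b without KAP1, KAP1 without Ring1b, or neither. Hox cluster genes had Ring1b at 92.3% of members and all protein-coding genes at 26.9%.

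Ring1b lay at promoters more than KAP1 did. Deposited promoters held 51.3% (50.5% to 52.2%) of Ring1b peaks and 18.5% (18.2% to 18.8%) of KAP1 peaks. Gene bodies held 24.8% of Ring1b and 38.5% of KAP1 peaks, and 23.9% and 43.0% lay between genes. Deposited promoters leave out genes with neither protein, so random placement was compared with windows of 1 kb around either end of any protein-coding gene, a choice made after seeing the data. These held 49.2% of Ring1b peaks against 4.43% of placed peaks, and 19.5% of KAP1 peaks against 3.93%.

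Peaks with the other protein were stronger and wider in both lists. KAP1 peaks that met Ring1b had a median score of 139 and a median width of 746 bp, against 91.7 and 485 bp for the others (permutation test, two-sided, p = 1e-05 for each, the smallest it can give). Ring1b peaks that met KAP1 had medians of 123 and 622 bp, against 99.1 and 487 bp (permutation test, p = 1e-05 for each). The quartiles of the Ring1b scores overlapped widely, with upper quartiles of 465 with KAP1 and 313 without. The widest Ring1b peak spanned Hoxb5 to Hoxb8 on chromosome 11 (96280598 to 96305880, 25283 bp) and held 2 KAP1 peaks. The next lay over Hoxa2 and Hoxa3 (chromosome 6, 52162675 to 52180759), Pax7, Tbx2 and Cbx8, with 7, 1, 4 and 6 KAP1 peaks inside. The widest 5 peaks thus covered Hox genes, regulators of muscle and limb development, and a Polycomb gene. Wider peaks meet others more often by chance, as the random shares by width above show.

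The last comparison asked which Ring1b sites were still called when KAP1 was deleted. Almost none were: 44 of 13516 Ring1b peaks, or 0.326% (0.237% to 0.437%), overlapped a knockout-list peak. Random placement gave a mean of 55.6, with a range of 33 to 80, so the observed count lay within that range. In the other direction, 44 of the 8928 knockout-list peaks (0.493%, 0.358% to 0.661%) met a Ring1b peak, 0.768 times the random mean of 57.3 and within its range of 32 to 86 (permutation test, p = 0.045, one-sided for a lower count, a side chosen after seeing the data). A placement by KAP1 and promoter class, chosen after seeing the data, put peaks at KAP1 into KAP1 peaks of the same promoter class. Other peaks at promoters went to any deposited promoter. The rest went anywhere on their chromosome, so they were not kept away from KAP1 or promoters. This placement gave a mean of 241 and a range of 198 to 283, and the ratio fell to 0.183 (permutation test, one-sided, p = 0.001, the smallest it can give). The strongest peaks of the knockout list lay near the end of chromosome X (170011452 to 170017892, score 3213, 20653 bp from Mid1), on chromosome Y, and on chromosome 9, 28625 bp from Ccr1. Chromosome 8 held 12.6% of the list, at 8.72 peaks per Mb, against 2.37 to 4.68 on the other autosomes. None of the 20 genes fixed for naming had a knockout-list peak at its promoter.

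**Figure D3:**
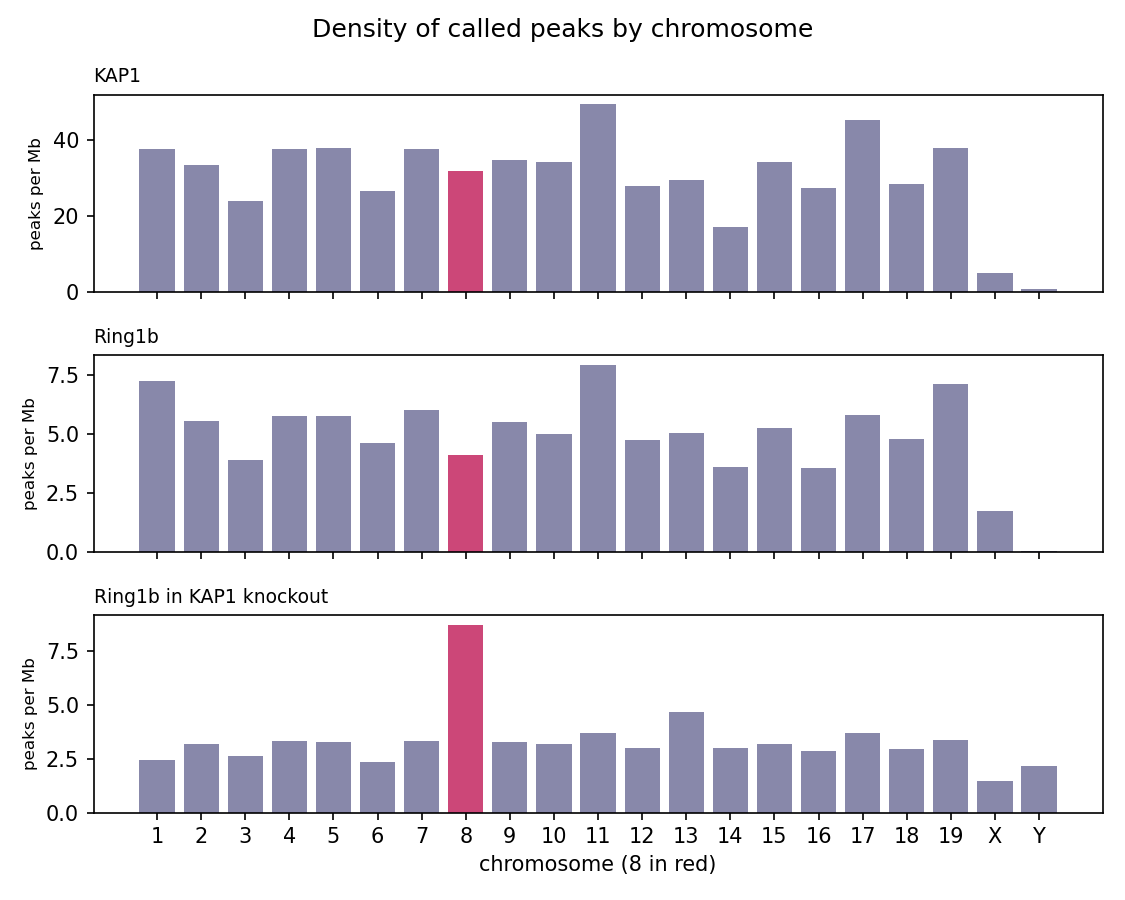
Peaks per Mb (vertical axes, 1 panel for each list) on each chromosome (horizontal axis). Chromosome 8, in red, had 8.72 knockout-list peaks per Mb, above the 2.37 to 4.68 of the other autosomes.

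The highest-scoring Ring1b peaks, in Glis1, over Mab21l1 and Nbea, and in Prkg1, Paqr9 and Ssbp2, were among those not called. The strongest of the 44 kept peaks lay in Tmem229a (chromosome 6, 24954375 to 24957157, score 2158), in Pdzd7, 939 bp from Ptma, 60154 bp from Zfp644, and in Pou2f1. Of the kept peaks, 43 overlapped KAP1 and 1 did not, among 10353 and 3163 Ring1b peaks. The odds ratio was 13.2 (1.82 to 95.8; Fisher's exact test, two-sided, p = 0.000222), and 13.7 (1.91 to 97.7) within deciles of score. Knockout-list peaks favoured KAP1 sites in general, with 13.6% at KAP1 against 2.57% for random placement, so this odds ratio does not measure retention of Ring1b. It rests on few peaks and did not pass with the upper scores of each list (1.396, Fisher's exact test, p = 1) or with an overlap of 50% of the peak (8.64, p = 0.0529).

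Of the 5653 genes with a Ring1b promoter peak, 43 (0.761%, 0.551% to 1.02%) had a knockout-list peak at the promoter. None of the 36 Hox cluster genes, 41 neuroectoderm, 38 mesoderm, 17 endoderm and 17 trophectoderm regulators with Ring1b was among them. In the 19 lists with Ring1b members, 2 genes were: the histone gene H3c15 and Rif1 of the pluripotency list, the latter named after its values were seen. No list differed from the other Ring1b genes (Fisher's exact test, lowest adjusted p = 0.989; 0 lists at an unadjusted p under 0.05). With so few genes counted, a list of this size cannot show fewer than the others. The count takes any knockout-list peak at the promoter, which need not overlap the Ring1b peak. At H3c15 the Ring1b peak (96238510 to 96239511) and the knockout-list peak (96239786 to 96240593) did not overlap. Within 5 kb of the promoters, replication-dependent histone genes passed (3 of 9, Fisher's exact test, adjusted p = 0.0424). The knockout list was made against another cell line, and no Ring1b list of untreated KAP1 fl/fl cells was used here, so the loss of calls is not a measured effect of the deletion.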

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

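The windows around gene ends and the placement by KAP1 and promoter class were chosen after seeing the data, and all other alternatives before. The overlap of Ring1b with KAP1 exceeded random placement (permutation test, p = 0.001) in each of the 8 alternatives run, with ratios from 2.82 to 37.7. The promoter odds ratio kept its direction and call, at 3.40 with the upper scores and 6.85 to 8.56 over gene ends. Promoter windows of 2.5 and 5 kb were not run for that test, since the reference used here gives no transcript starts for unbound genes. The differences in score and width kept theirs on autosomes.

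Knockout-list peaks met Ring1b 0.768 times as often as placed ones, within the range of the placements, and 0.183 times with placement by KAP1 and promoter class, below all of them.

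The share of Ring1b peaks kept moved to 0.0518% with an overlap of 50% of the peak, 1.01% within 1 kb and 0.0444% with the upper scores. The first and the last of these settings ended the call of kept peaks by KAP1 (odds ratios 8.64 and 1.396), where 7 and 3 kept peaks were left. Promoter shares of the KAP1, Ring1b and knockout lists moved to 22.5%, 56.7% and 6.37% within 2.5 kb, to 27.8%, 61.2% and 8.90% within 5 kb, to 24.2%, 62.7% and 5.66% with the upper scores, and to 19.5%, 49.2% and 7.29% at gene ends. Ring1b then met 2.83% and 6.63% of KAP1 only promoters within 2.5 and 5 kb, and KAP1 met 18.1% and 29.8% of Ring1b only promoters. Ring1b genes with a knockout-list peak moved to 1.58% within 2.5 kb, 3.14% within 5 kb and 0.133% with the upper scores; within 5 kb replication-dependent histone genes passed, with 3 of 9 (Fisher's exact test, adjusted p = 0.0424). Wider windows take in more peaks by construction.

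Of the 60 list tests, 46 kept direction and call with whole-gene classes, 4 lost the call, 3 gained it and 7 changed direction; against genes in any class 37 kept both, 8 lost the call, 4 gained it and 11 changed direction. Classes rebuilt from the peak lists gave the same 60 values, since the deposited classes follow from those peaks, and say nothing on stability. With whole-gene classes, clustered protocadherin genes turned in Ring1b only (odds ratio 0.429) and in shared (0.0477), by construction, since 1 of the 57 is in any of those tables. Tests without a call in either setting also turned: pluripotency-associated (1.27) and replication-dependent histone genes (1.53) in Ring1b only, imprinted (0.766) and Polycomb subunit genes (0.632) in KAP1 only, and housekeeping genes in shared (0.722). Against genes in any class, 5 calls turned and ended: totipotency-associated genes in shared (4.32), olfactory receptor genes in KAP1 only (1.75) and Ring1b only (1.05), and vomeronasal receptor genes in KAP1 only (6.14) and Ring1b only (1.958), lists with few members in that background. Without a call in either setting, trophectoderm regulators (0.721) and totipotency-associated genes (4.57) turned in Ring1b only, pluripotency-associated (0.570), imprinted (0.737) and Polycomb subunit genes (0.928) in KAP1 only, and housekeeping genes in shared (0.575). The cause was not tested for the others. No paired analysis was possible because each group held 1 library. Read depth was not given, which limits what an uncalled peak means.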

Other observations

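In this section, tests of KAP1 among Ring1b genes, chromosome X and the knockout list at histone genes were chosen after seeing the result. So were those of the missing Ring1b peaks (placement by KAP1 and promoter class included), of chromosome 8, and of zinc finger genes within deciles of gene length. KAP1 was not spread evenly over Ring1b promoters. Among genes with Ring1b, 20 of 36 Hox cluster genes had KAP1 (55.6%, 38.1% to 72.1%), against 86.5% of the others (odds ratio 0.196, Fisher's exact test, two-sided, adjusted p = 0.000131 over 19 lists). Wide Ring1b peaks can hold KAP1 outside the promoter window of 1 kb: the peak at Hoxa2, without KAP1 here, held 7 KAP1 peaks. Over whole genes, 26 of 39 Hox cluster genes are shared and 8 Ring1b only. Neighbouring genes can share a peak, as Hoxa9 and Hoxa10 share a Ring1b peak, which the test does not allow for. Clustered protocadherin genes, which encode neuronal adhesion proteins, had 17 of 28 (60.7%, odds ratio 0.244, Fisher's exact test, adjusted p = 0.00675). No other list passed: neuroectoderm regulators had 30 of 41 (73.2%, Fisher's exact test, adjusted p = 0.138). Pluripotency-associated genes had 22 of 23, the exception being Otx2, and trophectoderm regulators 16 of 17, the exception being Gata2; neither list passed (Fisher's exact test, adjusted p = 0.964 for both).

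Chromosome X carried few KAP1 peaks, 5.15 per Mb against an autosomal median of 34.2 and a minimum of 17.2. For Ring1b the values were 1.76 per Mb, 5.25 and 3.58. Of the 300 Ring1b peaks on chromosome X, 68 met KAP1 (22.7%, 18.1% to 27.8%), against 77.9% on autosomes. Fewer KAP1 peaks also make an overlap less likely by chance, and no random share is given here for chromosome X alone. The Polycomb gene Bcorl1, on chromosome X, had a Ring1b peak with a score of 3100 and no KAP1 peak at its promoter. In the knockout list, 13 of 37 replication-dependent histone genes bound by KAP1 or Ring1b had a promoter peak (35.1%, 20.2% to 52.5%), against 3.22% of other bound genes (odds ratio 16.3, Fisher's exact test, two-sided, adjusted p = 1.68e-09 over 20 lists). H1f2 and H2bc13 were among them, with scores of 63.0 and 88.2. Neighbouring histone genes can share a peak, which the test does not allow for. The knockout-list peak counted for H3c15 (chromosome 3, 96239786 to 96240593), for example, overlapped the neighbouring gene H2ac19 (96239779 to 96240374). No other list passed (Fisher's exact test, lowest adjusted p = 0.194, numbered zinc finger genes). Of all knockout-list peaks, 1211 of 8928 met a KAP1 peak (13.6%), against 2.57% of randomly placed ones (permutation test, one-sided, p = 0.001).

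Nearly all Ring1b peaks were missing from the KAP1 knockout list. Lower depth of the knockout library alone predicts that strong peaks survive. Of the upper 50% of Ring1b scores, 0.163% were kept (0.0813% to 0.291%), against 0.488% of the lower 50% (0.336% to 0.685%). This split cannot decide about depth, because the kept peaks were no more than random placement gives. Ring1b left in the control library, considered below, could also hide calls at strong peaks. Ring1b binding that needs KAP1 at the same site, as the whole cause, predicts that most peaks away from KAP1 survive. Of the 1456 Ring1b peaks with no KAP1 within 5 kb, 0 were kept (0 allows up to 0.206%), so local need alone does not account for them. Only 44 of 13516 Ring1b peaks were kept in all, within the range of random placement. The list therefore cannot show whether Ring1b needs KAP1 at sites that have both. A knockout library without Ring1b enrichment predicts overlap at chance level. With placement by KAP1 and promoter class the overlap was 0.183 times the random mean, below all placements. Those placements did not keep the other peaks away from KAP1, which can raise their mean. The cause of the deficit was not tested. Ring1b left in the control library, a candidate named below for promoters, could lower this overlap too. A library without enrichment cannot be told apart from other explanations on these lists. A loss of Ring1b from the whole genome after KAP1 deletion, or a difference between the cell lines, stays open, untested.

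Chromosome 8 held 8.72 knockout-list peaks per Mb, against 2.37 to 4.68 on the other autosomes, while its KAP1 and Ring1b densities, 31.9 and 4.13 per Mb, lay within the autosomal range. A few loci with many peaks would not leave an excess elsewhere, yet without its 2 fullest bins of 5 Mb the chromosome still held 6.44 per Mb, above the 4.69 that chromosome 13, the highest of the others, has when counted over such bins. A copy-number difference along the whole chromosome between the 2 cell lines predicts a broad excess. The median bin was 2.07 times that of the other autosomes, and 23 of 25 bins lay above it. An extra chromosome 8 in the KAP1 fl/fl line is therefore a hypothesis that may deserve a look in the reads; no biological explanation was tested.

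Knockout-list peaks lay at 370 of 6919 KAP1 only promoters and at 45 of 5235 shared ones with a listed KAP1 peak (odds ratio 6.52, 4.77 to 8.90). Higher KAP1 scores at KAP1 only promoters do not account for it: their median was 139 against 153, and the Mantel-Haenszel odds ratio within deciles of KAP1 score was 6.76 (4.94 to 9.27). Ring1b left in the control library, which would hide calls at Ring1b promoters, predicts fewer calls where Ring1b is strong, and the odds ratio of the upper against the lower 50% of Ring1b scores was 0.152 (0.0642 to 0.359, Fisher's exact test, two-sided, p = 2.78e-07). Residual Ring1b in the tamoxifen Ring1b fl/fl cells is thus a candidate source, although the same control still left 13516 vehicle peaks. Chromatin that differs between strong and weak Ring1b promoters stays open, untested.

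KAP1 is known for binding the 3' ends of zinc finger genes, and a hypothesis written before the test was that this list would show it. In genes of 5 kb or more whose strand followed from a deposited promoter, KAP1 peaks lay within 2 kb of the far end in 66 of 241 numbered zinc finger genes (27.4%) and 21.2% of the others, among 9181 genes in all. The odds ratio was 1.405 (1.05 to 1.87, Fisher's exact test, two-sided, p = 0.0253). Within deciles of gene length, a step added after that result, it was 1.20 (0.899 to 1.61), so the difference cannot be told apart from one of gene length.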
